A study of Mus musculus with 6 samples.

How the data were processed

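Single-cell RNA was measured with a droplet-based 10x Genomics protocol in 6 libraries of mouse anterior eye tissue, 2 from uninjured wild-type eyes, 2 from eyes burned with NaOH and transduced with an adeno-associated virus (AAV) carrying an empty vector, and 2 from burned eyes transduced with an AAV labelled as carrying a short hairpin RNA against Ifitm1. The labels state that lens, retina, iris and trabecular tissue were removed, that most of the conjunctiva was discarded, and that the tissue was digested with liberase and then trypsin. The time between burn and dissection is not given in the sources used here. Groups and replicate numbers were taken from the labels, and the replicate numbers were read as names of samples and not as pairs, since no source states a pairing. The sample sheet numbers are 8 to 10 for replicate 1 and 37 to 39 for replicate 2.

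The deposited values are unnormalised UMI counts per gene and barcode for 32285 genes, made with Cell Ranger 8.0.0 per the file headers. The submitters' processing notes name the mouse build GRCm38, whose gene coordinates are used here. The libraries held 10960 to 16230 barcodes with 98748415 to 166195414 UMIs, and the lowest total of a barcode was 500 UMIs in each library.

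Barcodes were kept with at least 500 UMIs, at least 300 detected genes and at most 20% mitochondrial UMIs. In the second empty-vector library 85.2% of barcodes passed, with 1574 of 10979 under 300 genes. In each other library 96.4% to 98.7% passed. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its automatic threshold was used in 3 libraries, where it marked 0.624% to 0.870% of the barcodes. In the other 3 libraries it marked under 0.5%, and the highest scores were removed instead at 0.8% per 1000 barcodes, which took 8.84% to 13.0% of the barcodes. Counts were scaled to 10000 per cell, 2000 variable genes and 30 principal components were used with 20 neighbours, and Leiden clustering (leidenalg 0.10.2) at resolution 1 gave 37 clusters of 69295 cells. Clusters were scored by the mean level of marker genes, standardised across clusters, with markers fixed in advance for 26 classes. The limits on naming were set after the clusters had been seen. A name needed at least 3 detected markers and a lead of at least 0.25 over the next class. It also needed a marker of that class among the 10 top genes of the cluster, and no other class with more of them. Outside the epithelium a score of at least 2 with a lead of at least 0.5 could replace this marker. Clusters with a median depth under 0.333 of the library median stayed unnamed if epithelial or without a class marker among their top genes. Of the 19 epithelial clusters, those without a clear subtype were pooled as epithelium of unnamed subtype. The stroma was taken from the clustering at resolution 0.5, a choice made after the data were seen, because its injured and uninjured cells formed different clusters at resolution 1.

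For each class with at least 20 cells in every library, UMIs were summed per library and tested with edgeR 4.0.16 (TMM normalisation, low-count filter, quasi-likelihood F test) in R 4.3.3, in 1 fit of all 6 libraries with group as the only term. P values were adjusted by the Benjamini-Hochberg (BH) method over the genes tested in a class, and an adjusted p under 0.05 was called a change. Levels are CPM, the UMI counts of a gene scaled to a common total per library and class with the TMM factors. Macrophages and neutrophils were tested in the 4 injured libraries alone. The 36 gene lists were fixed in advance and tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, for lists with at least 3 tested genes. Shares of cells are given with exact Clopper-Pearson 95% intervals, and a count of 0 with the share that 3 cells would give. These intervals and floors cover counting error only. Cell numbers per class were tested with edgeR against the number of kept cells. For shares of cells with UMIs of Ifitm1 or of proliferation genes, cells with at least 2000 UMIs were thinned to 2000, and a cell was counted as proliferating with at least 2 UMIs of a 30-gene list of G2 and M phase. A comparison of 2 against 2 values by exact permutation cannot give a p below 0.333, so such shares are given without a p, and no model was fitted to them.

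The genes named in the text are the Ifitm family; in the epithelium, the 12 largest and 12 smallest fold changes among genes with an adjusted p under 0.05, a mean log2 CPM of at least 4 and no overlap between the groups, and 5 and 5 in every other class, without predicted, mitochondrial, ribosomal, haemoglobin and sex-linked genes; up to 4 members of a called list and 2 of a list not called; and, where under 3 genes passed, the 6 smallest p values. Markers whose level defines a class were named where cell types are described. The groups, tests, lists, markers, filters and most alternatives were fixed before the data were examined.

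On simulated data with the dispersion of the real libraries, edgeR recovered 19% and 26% of 100 genes changed 2-fold in the epithelium and 76% and 77% of those changed 4-fold, for injury and for the shRNA label. In the limbal class it recovered 28% and 58% of 2-fold and 75% and 91% of 4-fold changes. Unchanged genes called by edgeR numbered 9 and 11 in the epithelium and 9 and 22 in the limbal class. DESeq2 called 48 and 54 unchanged genes in the epithelium and 10 and 15 in the limbal class. In the epithelium it recovered 53 and 46 of the 2-fold and 80 and 82 of the 4-fold changes, of 100 each. The DESeq2 counts of epithelial genes below are to be read beside these false calls. The alternatives were DESeq2 1.42.0, its size factors, no low-count filter, a stricter cell filter, doublets kept or removed at the expected rate, resolutions of 0.5 and 2, a replicate block, and each library left out. Corneal epithelium, keratocytes at resolution 1 and, with the uninjured libraries, macrophages and neutrophils were not tested because a library held under 20 cells. Counting used numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.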

Results

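Gene expression was measured in single cells from the front of the mouse eye, cornea and limbus with remaining conjunctiva, in 6 libraries from 3 groups of 2. The groups were uninjured eyes, eyes burned with NaOH and given an empty AAV vector, and burned eyes given an AAV labelled as carrying a short hairpin RNA against Ifitm1. Total depth was 124540296 and 102218584 UMIs in the uninjured libraries, 166195414 and 101373012 in the empty-vector libraries, and 112185248 and 98748415 in the libraries labelled shIfitm1. The kept cells numbered 10113 and 10478, 13895 and 9287, and 15771 and 9751 in the same order, and values given in sequence follow this order of groups and replicates. Adjusted p values of genes and classes come from edgeR's quasi-likelihood test with BH adjustment, and those of gene lists from camera with BH adjustment over the lists. Epithelial cells made up 73.5% and 79.9% of the uninjured, 71.9% and 63.8% of the empty-vector and 72.3% and 70.0% of the shIfitm1-labelled libraries. Stroma, macrophages, neutrophils, Schwann cells, pericytes and the endothelium of vessels made up most of the other named cells.

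The series asks what Ifitm1, a membrane protein of the interferon-induced transmembrane family, does in the limbal epithelium after a burn, so its level was measured first in every library. Ifitm1 was not called lower in the libraries labelled shIfitm1 than in the empty-vector libraries over all cells or in any class tested with all 6 libraries. Over all cells it stood at 390 and 427 CPM in the uninjured, 1995 and 1413 CPM in the empty-vector, and 1692 and 1566 CPM in the shIfitm1-labelled libraries. The means were 408 ± 26.2, 1704 ± 412 and 1629 ± 89.1 CPM (SD, n = 2 each). Ifitm1 (ENSMUSG00000025491) lies on chromosome 7 of GRCm38 at 140967221 to 140969825 on the plus strand, with 3 annotated transcripts. Ifitm2 and Ifitm3 lie beside it, and reads shared between these related genes were not separated here.

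In the epithelium Ifitm1 rose 4.30-fold with injury, from 419 and 444 CPM to 2130 and 1584 CPM (log2 fold change 2.10, 95% interval 1.58 to 2.63, edgeR BH-adjusted p = 0.00580), while the mix of epithelial classes also differed. In the shIfitm1-labelled libraries it stood at 1887 and 1743 CPM, a fold of 0.978 against the empty-vector libraries with a 95% interval of 0.689 to 1.39 (adjusted p = 0.959). In the limbal class the means were 843 ± 11.4, 1385 ± 53.1 and 1505 ± 235 CPM (SD, n = 2 each). The fold of the shIfitm1-labelled over the empty-vector libraries was 1.09 there (interval 0.830 to 1.42, adjusted p = 1.00), and the interval does not reach 0.5. The direction between these groups turned when 1 library was left out. Over the epithelium, where the log2 fold change was -0.03, it was 0.20 without the first empty-vector library and 0.03 without the second shIfitm1-labelled library, and over all cells it moved from -0.07 to 0.21 without the first empty-vector library. In the limbal class, where it was 0.12, it was -0.06 without the second shIfitm1-labelled library.

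Ifitm1 was highest in the conjunctival class and differed little there between groups, at 4406 and 3450, 4287 and 3597, and 3152 and 4091 CPM. It rose with injury 19.7-fold in the cycling epithelium, whose clusters differ between the groups, from 26.2 and 39.3 CPM to 622 and 671 CPM (adjusted p = 5.5e-05), and 9.45-fold in the stroma, from 32.4 and 47.1 CPM to 319 and 428 CPM (adjusted p = 0.0160). Between the labels the cycling class had a fold of 0.850 (95% interval 0.633 to 1.14, adjusted p = 0.618), and both shIfitm1-labelled libraries, at 552 and 547 CPM, lay below both empty-vector libraries. An Ifitm1 UMI was found in 51.6% and 50.0% of cycling cells with empty vector and in 41.3% and 41.1% with the label. The limbal injury fold was 1.64 and did not pass the test (interval of the log2 fold change 0.32 to 1.11, adjusted p = 0.101). After thinning each cell to 2000 UMIs, an Ifitm1 UMI was found in 12.2% and 14.2% of uninjured epithelial cells, 68.7% and 64.8% of those with empty vector and 51.6% and 64.2% of those labelled shIfitm1. The Clopper-Pearson 95% intervals were 67.8% to 69.6% and 63.6% to 66.1% with empty vector and 50.7% to 52.6% and 63.1% to 65.4% with the label. The same share was 2.08% and 0%, 15.1% and 3.92%, and 9.52% and 6.17% in Schwann cells, which were taken as a type without the gene. The 0 was found in 25 Schwann cells, which allows up to 12%. Median depth before thinning was 11606, 9621, 10128, 11983, 7308 and 9605.5 UMIs in epithelium and 2808, 2483, 4123, 5500, 2858.5 and 4694 UMIs in Schwann cells. Of the other family members in the epithelium, Ifitm3 rose with injury 9.93-fold (adjusted p = 0.00918) and Ifitm2 2.30-fold (adjusted p = 0.0108), while Ifitm10 fell by 0.62 on the log2 scale (adjusted p = 0.0290). Ifitm6 had 0 counts in the uninjured libraries and 33 with empty vector, which is at least 8.95-fold higher against a floor of 3 counts over the group (adjusted p = 0.0111). Ifitm5 had a log2 fold change of 0.69 (adjusted p = 0.366). Ifitm7 was not tested. None of these passed the test between the shIfitm1-labelled and the empty-vector libraries, where Ifitm3 had a log2 fold change of -0.63 (adjusted p = 0.603).

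**Figure D1:**
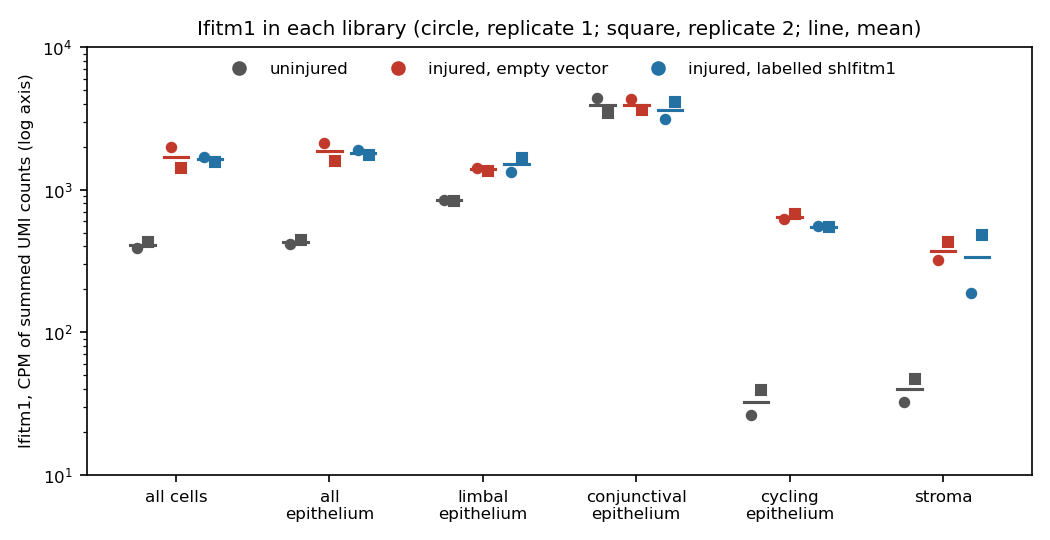
Ifitm1 level (CPM, log axis) in each library by cell class, with circles for replicate 1, squares for replicate 2 and a line at the group mean. In the epithelium both injured groups lie above the uninjured libraries at 419 and 444 CPM, and the libraries labelled shIfitm1, at 1887 and 1743 CPM, lie within the range of the empty-vector libraries.

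The first comparison, injured eyes with empty vector against uninjured eyes, asks how the tissue responds to the burn, and it covers burn and vector together because the uninjured eyes are labelled without a vector. Neutrophils and macrophages, rare in the uninjured libraries, rose in share. Neutrophils were 0.0494% and 0% of uninjured and 3.47% and 6.45% of empty-vector cells, where the 0 of 10478 cells allows up to 0.0286% (edgeR log2 change 7.60, BH-adjusted p = 0.0301). Macrophages and monocytes went from 0.376% and 0.115% to 2.79% and 3.65% (log2 change 3.71, adjusted p = 0.0176). This class was not separated from dendritic cells, since its cluster has H2-Aa, Cd74 and H2-Eb1 among its top genes, and at Leiden resolution 2 a dendritic cluster of 2 and 1, 67 and 55, and 67 and 61 cells stood apart. By lineage, the epithelium was 73.5% and 79.9% of uninjured and 71.9% and 63.8% of empty-vector cells.

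In all, edgeR called 7 of 16 class shares with injury. Beside the neutrophils and macrophages these were the limbal (adjusted p = 0.0232), conjunctival (adjusted p = 0.0120) and corneal (adjusted p = 0.0120) epithelium, keratocytes (adjusted p = 0.0356) and unnamed clusters (adjusted p = 0.0356). The stroma, grouped at the coarser resolution, was 5.67% and 5.09% of uninjured and 3.41% and 3.78% of empty-vector cells. The epithelial and keratocyte clusters formed partly by injury, so a cell that changed its genes could change its class, and the sizes of these classes are given only beside gene levels. Between the shIfitm1-labelled and empty-vector libraries edgeR called 0 of 16 classes, with 2 at an unadjusted p under 0.05, the corneal class (adjusted p = 0.0703) and the keratocytes (adjusted p = 0.212). Over both comparisons together the count of 7 became 1 without the first uninjured library and 0 without the second uninjured, the first empty-vector or the second empty-vector library. It became 9 and 10 without the first and the second shIfitm1-labelled library. Here and below, a group left with 1 library is assumed to vary like the others. Epithelium of unnamed subtype made up 44.5% and 49.1%, 34.8% and 27.7%, and 45.4% and 32.2% of cells. Low-depth unnamed clusters made up 18.1% and 13.4%, 14.2% and 18.1%, and 14.3% and 10.8%, and other unnamed clusters 0.682% and 0.181%, 3.27% and 3.80%, and 2.38% and 6.04%.

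In the injured epithelium Lypd2, Slurp1 and Piezo2 fell, and Krt17, Actn1, Msn and Gpha2 rose. The mix of cells differed too, with the limbal class at 1.73% and 1.53% of uninjured and 13.1% and 17.9% of empty-vector cells, the conjunctival class at 1.04% and 1.19% against 12.5% and 7.33%, and the corneal class at 19.1% and 18.6% against 0.00720% and 0.0108%. Lypd2 and Slurp1, neighbouring genes of Ly6 family proteins on chromosome 15, fell by 5.12 and 4.30 on the log2 scale (adjusted p = 0.0110 and 0.0129, n = 2 each). Lypd2 went from 4228 and 5703 CPM to 132 and 154 CPM and Slurp1 from 2819 and 3884 CPM to 160 and 180 CPM. Krt17, a keratin of wounded epithelium, rose 60.7-fold, from 18.1 and 17.1 CPM to 931 and 1202 CPM (log2 fold change 5.92 ± 0.52 SE, adjusted p = 0.00485). Gpha2, a marker of the outer limbus, rose 9.22-fold, from 76.3 and 63.2 CPM to 524 and 763 CPM (adjusted p = 0.00816). Within the limbal class Gpha2 did not pass the test, at 2420 and 2012 against 2859 and 2779 CPM (adjusted p = 0.399), and its rise over the epithelium was not separated from the higher share of limbal cells. Krt14, a keratin of basal cells, rose 6.64-fold in the epithelium (adjusted p = 0.00599). The chemokine gene Ppbp had the largest rise among the genes named by rule, from 0.0519 and 0.282 CPM to 124 and 160 CPM (log2 fold change 9.77 ± 0.81 SE, adjusted p = 0.00392).

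Of 17171 genes tested in the epithelium, 3470 changed, 1834 higher and 1636 lower with injury. The 12 largest rises among those passing the naming rule had log2 fold changes from 9.77 down to 3.95. After Ppbp they were Esp6 (7.53), the actin crosslinker Actn1 (6.02), Krt17, the membrane-cytoskeleton linker Msn (5.34), the ectonucleotidase gene Nt5e (5.24), the transcription factor Sox4 (4.84), the potassium channel gene Kcnq5 (4.44), the homeobox gene Barx2 (4.25), Ly6a (4.18), the TGF-beta binding protein gene Ltbp1 (4.02) and the tetraspanin Cd63 (3.95). The 12 largest falls were Csgalnact1 (-5.23), Lypd2, the mechanosensitive channel gene Piezo2 (-5.06), Lsamp (-4.75), Slurp1, the transglutaminase gene Tgm2 (-4.20), the cation channel gene Trpm3 (-4.18), Aldh1a1 (-4.09), Ly6g6c (-4.09), Frmd4a (-4.03), Fras1 (-3.73) and Ano4 (-3.70). Adjusted p values of these 24 genes lay between 0.00294 for Barx2 and 0.0235 for Ly6g6c. The count of changed genes rested on single libraries: it was 47 without the first and 0 without the second uninjured library, 1592 without the first and 909 without the second empty-vector library.

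**Figure D2:**
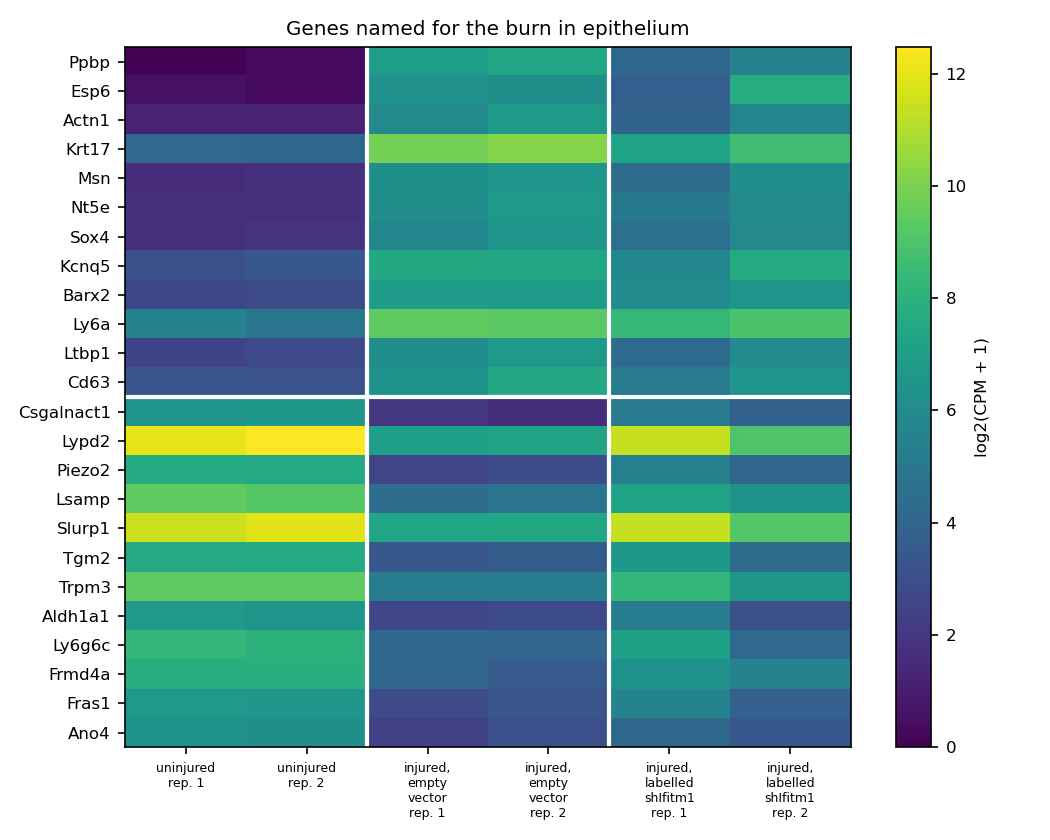
Level, as log2 of CPM plus 1, of the 12 most raised and 12 most lowered named epithelial genes in each of the 6 libraries. The uninjured and empty-vector libraries lie at opposite ends for each gene, as for Lypd2 at 4228 and 5703 against 132 and 154 CPM, and the first library labelled shIfitm1 lies between them.

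Among the gene lists fixed in advance, 17 of 36 were called in the injured epithelium with the preset correlation, and 0 with a correlation estimated from the data. Division genes were higher. Of 30 genes of G2 and M phase 16 were higher over all genes tested, and 21 higher with 1 lower adjusted over the list alone (list adjusted p = 1.4e-05, adjusted p = 0.743 with an estimated correlation). Among them were Cenpa (1.38 on the log2 scale), Cdca3 (1.12), Ccnb2 (0.91) and Birc5 (0.92). Of 30 genes of S phase 3 were higher, E2f8, Gins2 and Mcm7, and 0 adjusted over the list alone (list adjusted p = 0.000122, adjusted p = 0.743 with an estimated correlation). Immediate early genes went the other way, with 10 of 26 lower and 15 adjusted over the list alone (list adjusted p = 1.4e-05, adjusted p = 0.689 with an estimated correlation). Btg2 fell by 1.75, from 1059 and 1249 CPM to 443 and 242 CPM, and on the log2 scale Ccn1 fell by 2.22, Jund fell by 1.20 and Ier2 fell by 0.92. These genes also respond to tissue dissociation.

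The hypoxia and glycolysis list had 15 of 23 genes higher and 1 lower, and 16 higher and 1 lower adjusted over the list alone (list adjusted p = 0.000122, adjusted p = 0.659 with an estimated correlation). The lactate exporter Slc16a3 had a log2 fold change of 5.84, the mitophagy gene Bnip3 4.07, the glycolytic Pfkp 2.46 and Tpi1 1.36. The outer limbus list had 7 of 10 genes higher and 1 lower, and 8 and 1 adjusted over the list alone (list adjusted p = 0.000920, adjusted p = 0.659 with an estimated correlation), with Krt17, Gpha2, Ifitm3 and Cd63. The conjunctival list had 8 of 11 higher, also 8 over the list alone (list adjusted p = 0.01002, adjusted p = 0.454 with an estimated correlation), among them Krt7 (3.92), Krt19 (3.17), Ltf (6.17) and Lcn2 (3.63). The Ifitm family had 4 of 6 higher and 1 lower, the same over the list alone (list adjusted p = 0.0109, adjusted p = 0.535 with an estimated correlation). Wound keratins and alarmins had 5 of 17 higher and 7 over the list alone, including Il1rn and S100a9 (list adjusted p = 0.00605, adjusted p = 0.659 with an estimated correlation). Metalloproteinases and their inhibitors had 7 of 13 higher and 8 over the list alone, including Timp1 and Timp2 (list adjusted p = 0.00608, adjusted p = 0.659 with an estimated correlation).

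Of the macrophage activation list 7 of 14 genes were higher and 1 lower, and 10 and 1 adjusted over the list alone (list adjusted p = 0.000127, adjusted p = 0.454 with an estimated correlation). Its members include genes found in epithelial cells as well, with the fatty acid binding protein gene Fabp5 going from 489 and 817 CPM to 7068 and 5243 CPM and Arg1 from 77.6 and 75.2 CPM to 382 and 271 CPM, beside Gpnmb with a log2 fold change of 5.35. Chemokines and NF-kB targets had 7 of 26 higher and 1 lower, and 13 and 1 over the list alone (list adjusted p = 0.0357, adjusted p = 0.743 with an estimated correlation). EMT regulators had 5 of 10 higher, also 5 over the list alone (0.0237, and adjusted p = 0.454 with an estimated correlation), and activated fibroblast genes 10 of 19 higher and 1 lower, and 13 and 2 over the list alone (0.00563, and adjusted p = 0.743 with an estimated correlation). The summed level of the activated fibroblast list was 210 and 195 CPM in uninjured and 203 and 488 CPM in empty-vector libraries. An epithelial cluster with Acta2, Tpm1 and Cald1 among its top genes held 0 and 0 uninjured, 72 and 786 empty-vector and 8 and 11 shIfitm1-labelled cells. Summed levels overlapped between the groups also for the chemokine list (1116 and 1294 against 1542 and 673 CPM), EMT regulators (543 and 485 against 504 and 625 CPM), the conjunctival list (3117 and 2593 against 3831 and 2350 CPM) and wound keratins and alarmins (16155 and 23502 against 27413 and 21612 CPM). Markers of other cells were higher as well, with summed levels in the empty-vector libraries of 185 and 188 CPM for macrophages, 24.9 and 16.7 CPM for neutrophils, 16.8 and 14.2 CPM for vessels and 2322 and 1277 CPM for conjunctiva and goblet cells, the last against 916 and 954 CPM in uninjured libraries. They passed for macrophages in 9 of 11 genes and 11 over the list alone (list adjusted p = 1.5e-05), and neutrophil markers in 3 of 8 and 7 over the list alone (0.000920), vessel markers in 3 of 8 and 4 over the list alone (0.0170), and conjunctiva and goblet markers in 5 of 6 and 5 over the list alone (0.0109). With an estimated correlation the adjusted p was 0.659 for the neutrophil markers and 0.454 for the others. Lyz2, a gene of macrophages, went from 0.135 and 0.388 CPM to 2.01 and 2.24 CPM. The summed macrophage markers stood at 100 and 90.4 CPM in uninjured libraries. Apoe alone stood near the sums, at 91.1 and 81.8 CPM in uninjured and 165 and 167 CPM in empty-vector libraries.

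The lists of corneal differentiation (9 of 20 lower and 3 higher, list adjusted p = 0.118), basal and stem cell regulators (2 of 18 higher and 3 lower, 0.591) and the interferon response (1 of 33 higher and 4 lower, 0.137) were not called in the epithelium. Nor were epidermal differentiation (2 of 15 higher and 4 lower), antigen presentation (4 of 14 higher and 1 lower), keratocyte identity (4 of 11 lower), unfolded protein (5 of 22 higher and 3 lower) and oxidative phosphorylation (0 of 38), or the others of the 36. Within corneal differentiation the members moved apart, since Car12 (4.10) and Clu (3.57) rose while Lypd2, Slurp1 and Aldh3a1 fell. For oxidative phosphorylation the median log2 change was -0.03 while mean and test were positive. For oxidative stress the median was 0.25 while mean and test were negative, and for the Notch pathway the test was negative while median (0.01) and mean (0.07) were positive. The list calls numbered between 18 and 20 when single libraries were left out.

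In the limbal class, injury changed fewer genes. Clusterin, Clu, rose 19.0-fold, from 83.8 and 92.9 CPM to 974 and 2382 CPM (log2 fold change 4.25 ± 0.66 SE, adjusted p = 0.0323), and the steroid enzyme gene Hsd17b2 7.45-fold, followed by Cstdc5 (2.70), Cmah (2.54) and Nt5e (2.21). Clu is also a top gene of the epithelial cluster of 0 and 0 uninjured and 72 and 786 empty-vector cells. Free RNA of that cluster was not separated from the limbal rise of Clu. Trpm3 fell from 567 and 609 CPM to 30.2 and 38.1 CPM (-4.10, adjusted p = 0.0176), and the other largest falls were Lypd2 (-4.02), the natriuretic peptide receptor gene Npr3 (-3.48), Necab1 (-3.35) and Tppp3 (-3.21). Lypd2, Trpm3 and Necab1 stood at 4228 and 5703, 692 and 666, and 90.7 and 71.5 CPM in the uninjured epithelium as a whole, and free RNA of the corneal class, nearly absent after injury, was not separated from these limbal falls. Npr3 and Tppp3 were higher in uninjured limbal cells, at 64.7 and 76.8 and at 190 and 133 CPM, than in the epithelium as a whole, at 34.3 and 32.6 and at 14.1 and 13.3 CPM. The limbal markers that define the class stayed high in every library: Gpha2 was at 2420 and 2012, 2859 and 2779, and 2719 and 2827 CPM and Krt15 at 3524 and 3641, 3376 and 2894, and 4140 and 3513 CPM. Of 12881 genes 136 changed, 40 higher and 96 lower. The count was 4 and 0 without the first and the second uninjured library, 247 and 27 without the first and the second empty-vector library, and 365 and 270 without the first and the second shIfitm1-labelled library. DESeq2 called 393.

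Of the gene lists, 6 were called in the limbal class, and 0 with an estimated correlation. Antigen presentation had 0 of 14 members passing over all genes and 6 adjusted over the list alone, with H2-K1 at 0.88 and Psmb10 at 1.09 on the log2 scale (list adjusted p = 0.000268, adjusted p = 0.866 with an estimated correlation). The Wnt and BMP list was lower, with the Wnt antagonist Dkk3 (-1.16, adjusted p = 0.0207) as its 1 member of 21 passing and 4 adjusted over the list alone (list adjusted p = 0.0186, adjusted p = 0.866 with an estimated correlation). Lgr5 and Wnt6 had log2 fold changes of -2.91 and -2.11 that did not pass (adjusted p = 0.0894 and 0.0920). Corneal differentiation was lower, with 1 of 19 genes lower and 1 higher, and 8 lower and 1 higher adjusted over the list alone (0.0245, and adjusted p = 0.866 with an estimated correlation). Dkk3 is among the top genes of a corneal cluster at Leiden resolution 2 with 569 and 808 uninjured and 1 and 0 empty-vector cells. Free RNA of corneal cells was not separated from the fall of Dkk3 or of the corneal list. Immediate early genes, with summed levels that overlapped (23175 and 17527 against 22378 and 9298 CPM), were lower with Egr3 (-1.97) as the 1 passing of 26, also 1 adjusted over the list alone (0.0245, and adjusted p = 0.878 with an estimated correlation). Macrophage activation was higher with Fabp5 (1.71) as the 1 passing of 10 and 3 over the list alone (0.0292), and vessel markers had 0 of 3 passing either way (0.0385), each with adjusted p = 0.866 with an estimated correlation. The summed level of 4 macrophage markers in limbal cells went the other way, at 2033 and 1568 CPM in uninjured and 750 and 538 CPM in empty-vector libraries. It is not given by gene here, and Apoe alone stood near such sums in the epithelium and the stroma. The lists numbered 1 without the second uninjured and 4 without the first empty-vector library.

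In the conjunctival class edgeR called 0 of 12599 genes with injury, with 1344 at an unadjusted p under 0.05 and 181 by DESeq2. It called 78 and 88 without the first and the second shIfitm1-labelled library and 11 without the second empty-vector library. The genes nearest to passing were Cd109 (-2.36) and Grip1 (2.84), both with adjusted p = 0.0816, then Dnm3 (2.43), Rasgrf1 (-1.81), Ooep (-1.19) and Fmo2 (-1.68), with adjusted p = 0.0880. The cycling epithelium showed a broad change, with 3222 of 13046 genes, 1646 higher and 1576 lower. Actn1 (6.47), Msn (5.95), Krt17 (5.85), Ly6a (5.42) and Cstdc5 (5.16) rose most, and Csgalnact1 (-4.70), Piezo2 (-4.60), Lsamp (-4.39), the carboxylesterase gene Ces1d (-4.37) and Sphkap (-4.35) fell most. A cycling cluster of 429 and 592 uninjured cells held 1 and 6 cells of the empty-vector libraries, so the classes compared differ in their clusters. The count was 1288 and 1311 without the first and the second uninjured library.

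In the injured stroma keratocan, Kera, a proteoglycan of the clear cornea, fell from 9171 and 8603 CPM to 646 and 403 CPM (-4.08 ± 0.67 SE, adjusted p = 0.0196), with Angptl7 (-4.18), the endothelin receptor gene Ednrb (-4.59), Mamdc2 (-4.08) and Lypd2 (-4.84), the last a surface epithelial gene seen here at 77.2 and 69.7 CPM. The acute-phase gene Saa3 went from 3 counts to 48304 counts, a ratio of 14502 with a counting interval of 4962 to 70325 (adjusted p = 0.00913), to 5551 and 3628 CPM. Lcn2, an iron-sequestering alarmin, had 0 counts in the uninjured and 3675 in the empty-vector stroma, at least 1103-fold higher against a floor of 3 counts over the group (adjusted p = 0.00734). Chil1 rose to 3562 and 5981 CPM from 6.27 and 1.75 CPM (adjusted p = 0.00546), and Serpina3n (7.13) and the deiodinase gene Dio2 (6.83) followed. Of 12723 genes 1325 changed, 791 higher and 534 lower.

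By list, 19 were called in the stroma with injury and 0 with an estimated correlation. Chemokines and NF-kB targets had 9 of 19 higher and 16 adjusted over the list alone, with Cxcl5 at 22.6 and 5.51 CPM against 517 and 735 CPM and Cxcl2 and Icam1 (list adjusted p = 1.3e-07, adjusted p = 0.508 with an estimated correlation). Hypoxia and glycolysis had 10 of 22 and 14 over the list alone (1.4e-06) and metalloproteinases 6 of 13 and 8 over the list alone (5.9e-05), each with adjusted p = 0.508 with an estimated correlation. Basement membrane and adhesion had 7 of 22 and 9 over the list alone (6.5e-05, and adjusted p = 0.270 with an estimated correlation), with the matrix protein genes Tnc (4.78) and Postn (2.63). Macrophage activation had 7 of 10 and 8 over the list alone (2.1e-05), and wound keratins and alarmins 4 of 12 and 6 over the list alone (0.000359), each with adjusted p = 0.270 with an estimated correlation. Activated fibroblast genes had 9 of 19 higher and 1 lower, and 11 and 4 over the list alone (0.0180, and adjusted p = 0.533 with an estimated correlation), among them Acta2 (3.81) and Thbs2 (1.49). Keratocyte identity had 5 of 12 lower and 1 higher, the same over the list alone (0.0276, and adjusted p = 0.508 with an estimated correlation), with summed levels of 60308 and 56731 against 41298 and 36418 CPM, and the unfolded protein list 5 of 21 lower and 1 higher, and 6 and 2 over the list alone (0.0348, and adjusted p = 0.508 with an estimated correlation). The other 10 lists called were neutrophil markers (3 of 3, adjusted p = 0.000865), antigen presentation (2 of 13, 0.00472), EMT regulators (5 of 11, 0.0117), G2 and M phase (0 of 21, 0.0160), outer limbus (4 of 9 with 1 lower, 0.0180), the Ifitm family (2 of 4, 0.0290), basal and stem cell regulators (2 of 16, 0.0348), immediate early genes (3 of 26, 0.0348), oxidative phosphorylation (0 of 38, 0.0348) and conjunctival genes (2 of 7, 0.0490), all higher. Over the list alone these were 3, 4, 7 with 1 lower, 0, 5 with 1 lower, 3, 2, 5, 0 and 3, and with an estimated correlation the adjusted p was 0.727 for immediate early genes and oxidative phosphorylation and 0.508 for the others. Keratins of epithelium were higher in the injured stroma too: Krt14 rose from 19.7 and 15.0 CPM to 177 and 120 CPM (adjusted p = 0.0110) and Krt17 from 2 counts to 206 (adjusted p = 0.00734), while Krt5, named after its values were seen, did not pass (log2 fold change -0.37, adjusted p = 0.713). Free epithelial RNA was not separated from the stromal counts or from these lists. An unnamed cluster at resolution 1, with trabecular meshwork as its best score, has Col3a1, Mmp3, Postn and Tnc among its top genes. It held 66 and 6 uninjured against 88 and 77 empty-vector cells, and the mix of stromal cell types was not separated from these changes. The summed level of macrophage markers in the stroma was 863 and 961 CPM in uninjured and 338 and 371 CPM in empty-vector libraries. Apoe alone stood near these sums there, at 852 and 947 CPM in uninjured and 301 and 317 CPM in empty-vector libraries. The sum was therefore not read as a level of macrophages. Summed levels of immediate early genes, wound keratins and alarmins, antigen presentation and activated fibroblast genes overlapped between the groups.

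The count of stromal genes changed by injury was 61 and 0 without the first and the second uninjured library, 13 and 16 without the first and the second empty-vector library, and 2069 and 2083 without the first and the second shIfitm1-labelled library.

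Smaller classes gave few calls with injury. In pericytes the chemokine gene Cxcl2 (3.90, adjusted p = 0.0481) and Gfpt2 (3.62, adjusted p = 0.0216) rose among 5816 genes. This count of 2 was 0 without either uninjured library or the first empty-vector library, 3 without the second empty-vector library, 164 and 129 without the first and the second shIfitm1-labelled library, and 18 by DESeq2. In vascular endothelium 3 of 7084 genes fell: Cmss1 (-1.51), Apol10b (-2.77), and Gm42418 (-1.68), which lies outside the naming rule and was named after its values were seen. Cmss1 is also among the top genes of 4 low-depth unnamed clusters and Gm42418 took 128800 and 147730 CPM of the uninjured endothelium, so a difference in the quality of barcodes was not separated from these falls. This count of 3 was 0 without the first uninjured or either empty-vector library, 196 and 262 without the first and the second shIfitm1-labelled library, and 61 by DESeq2. In Schwann cells edgeR called 0 of 6776 genes, with 655 at an unadjusted p under 0.05 and 31 by DESeq2. It called 13 without the first empty-vector library, and 215 and 143 without the first and the second shIfitm1-labelled library. The 6 smallest p values there, each with adjusted p = 0.0727, belonged to Mki67, Cenpf, Krt17, Ly6a, Tm4sf1 (2.27) and Slc10a6 (-1.87). Mki67 had 1 count against 406, a ratio of 88.5 with a counting interval of 15.8 to 3505, and Cenpf 1 count against 187, a ratio of 40.8 with an interval of 7.23 to 1619. Krt17 had 0 counts against 222, at least 16.1-fold higher, and Ly6a 0 against 166, at least 12.1-fold higher, against a floor of 3 counts over the group. Krt17 and Ly6a also rose in the injured epithelium, and free epithelial RNA was not separated from the counts of Schwann cells.

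The second comparison, libraries labelled shIfitm1 against libraries with empty vector, asks whether the hairpin changed the response to the burn. Since Ifitm1 was not called lower in the libraries labelled shIfitm1, the comparison is between labels and not between levels of the gene. No single gene passed in the epithelium as a whole. The libraries labelled shIfitm1 had Lypd2 at 2708 and 530 CPM against 132 and 154 CPM and Slurp1 at 2644 and 580 CPM against 160 and 180 CPM (log2 fold changes 3.50 ± 0.73 and 3.25 ± 0.68 SE, both adjusted p = 0.436). Krt17 stood at 151 and 402 CPM against 931 and 1202 CPM (-1.95 ± 0.44 SE, adjusted p = 0.436). In each case both shIfitm1-labelled libraries lay on the uninjured side of both empty-vector libraries. The mix of epithelial clusters differed too, and it was not separated from these levels. The corneal class held 1 and 1 cells with empty vector and 602 and 26 with the label. An epithelial cluster of 1600 and 2083 uninjured cells held 1 and 0 with empty vector and 1013 and 40 with the label.

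EdgeR called 0 of 17171 epithelial genes, with 1723 at an unadjusted p under 0.05 and 276 called by DESeq2, and 0 of 18704 over all cells, with 1732 and 336. The smallest p values belonged to the retinoic acid binding protein gene Crabp2 (-1.78), the channel gene Trpm6 (-1.05), Sphkap (2.11), the immediate early gene Ccn1 (1.01), Cyfip2 (1.38) and Csgalnact1 (3.21), each with adjusted p = 0.377. Without the second shIfitm1-labelled library 600 epithelial genes were called, and 1 without the first empty-vector library. Across all tested genes the log2 fold changes of the injury and of the label had a covariance of -0.455 and opposite signs in 77.0% of genes, where both comparisons share the empty-vector libraries. In 20 simulations of unchanged groups with this sharing the covariance lay between -0.0826 and -0.0717. The simulated share of opposite signs was 71.3% to 75.5%, but it cannot serve as a reference. The normalisation factors were applied to the simulated counts again after being used to draw them, which shifts all simulated fold changes. The covariance is not moved by such a shift. Without the first shIfitm1-labelled library 64.9% of genes had opposite signs. In the limbal class 63.3% of genes had opposite signs, and the covariance was -0.122 against -0.0523 to -0.0422 in the simulations. Genes are not independent replicates, and the covariance was -0.247 without the first and -0.751 without the second shIfitm1-labelled library, and -0.760 without the first empty-vector library.

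The 2 libraries labelled shIfitm1 did not stand at the same distance. On a scale for each of the 3470 injury genes where 0 is the uninjured and 1 the empty-vector mean, the median position was 0.509 in the first (quartiles 0.326 to 0.689) and 0.821 in the second (0.652 to 0.961). Over the 136 limbal genes the medians were 0.540 and 0.821, and over the 1325 stromal genes 0.521 and 0.866. Because the genes were picked for their difference in the empty-vector libraries, other libraries fall below 1 by selection as well. Neutrophils were 0.495% of cells in the first and 6.06% in the second library.

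**Figure D3:**
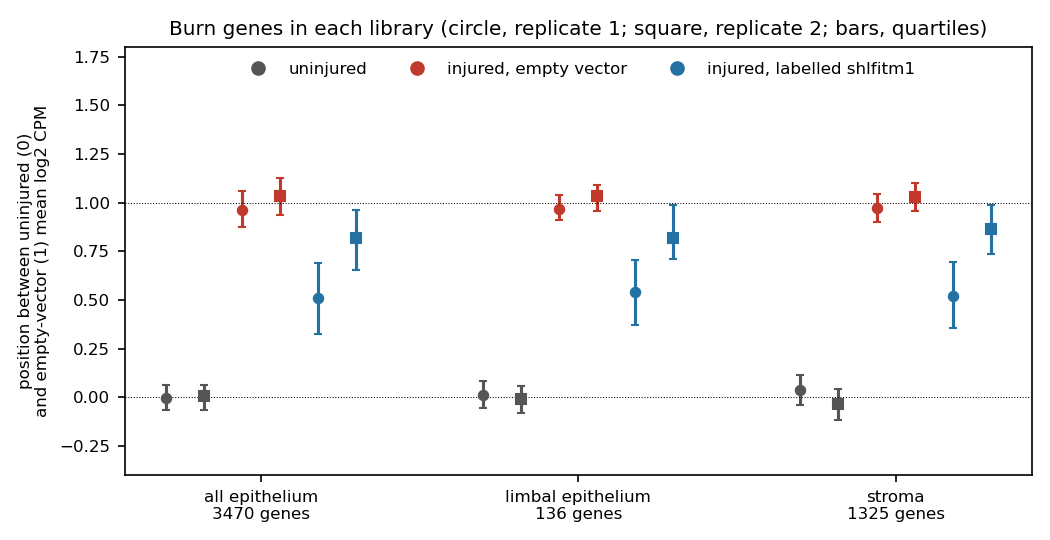
Median position of each library, with quartiles as bars, over the genes changed by injury in epithelium, limbal class and stroma, where 0 is the uninjured and 1 the empty-vector mean. The first library labelled shIfitm1 lies near the middle, at 0.509 in the epithelium, and the second at 0.821.

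Several lists were called in the epithelium between these labels, 7 with the preset and 0 with an estimated correlation (adjusted p = 0.862 for each), and no member passed over all genes. Genes of G2 and M phase were lower, 14 of 30 adjusted over the list alone with a median of -0.66 (list adjusted p = 1.3e-13), and their summed level was 2070 and 1886 CPM with empty vector and 989 and 1558 CPM with the label. S phase genes were lower with a median of -0.55 and 0 of 30 over the list alone (5.1e-07), with summed levels of 1073 and 792 CPM against 488 and 853 CPM that overlapped. Immediate early genes were higher, 11 of 26 over the list alone with a median of 0.98 (9.4e-12), including Jund, Btg2 and Ier2, and their summed level of 17495 and 15468 CPM stood beside 17638 and 14879 CPM in the uninjured libraries. Corneal differentiation was higher, 4 of 20 over the list alone (0.00277), with Lypd2, Slurp1, Aldh3a1 and Tkt. The mix of epithelial clusters was not separated from these list calls. Immediate early genes also respond to tissue dissociation, which was not separated from their levels between the labels here or in the limbal class. Oxidative phosphorylation (median 0.23, 0 of 38 over the list alone, 0.00242, summed levels of 9650 and 7789 CPM against 10960 and 9268 CPM) and keratocyte identity (median 0.87, 0 of 11, 0.0319) were higher, and the mitochondrial genome lower (median -0.14, 0 of 13, 0.0278). The keratocyte list summed to 11217 and 11182, 2436 and 1773, and 7776 and 3601 CPM in the epithelium. Stroma markers summed to 735 and 749, 623 and 686, and 1049 and 653 CPM there. The call was therefore not read as a gain of keratocytes. For the interferon response the median was 0.01 and the test positive while the mean was -0.04. For the Notch pathway the median was 0.04 while mean and test were negative, and for macrophage activation the mean was 0.04 while median and test were negative. The lists called numbered 11 without the first empty-vector library and without the second shIfitm1-labelled library, and 4 without the second empty-vector library.

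Limbal cells gave 0 of 12881 genes by edgeR between the labels, with 584 at an unadjusted p under 0.05 and 3 by DESeq2. EdgeR called 3 and 14 without the first empty-vector and the second shIfitm1-labelled library. The smallest p values were those of Sprr1a (-1.12), Fmo1 (0.82), the glutathione transferase gene Gsta2 (1.11) and Dab1 (0.95), with adjusted p = 0.705, and of Rtl3 (0.84) and the replication gene Timeless (-1.64), with adjusted p = 0.823. S phase was the list with the smallest p, lower with 9 of 30 adjusted over the list alone (list adjusted p = 4.4e-16, adjusted p = 0.281 with an estimated correlation), with Mcm3 at 13.2 and 12.9 CPM against 8.21 and 4.99 CPM, and Clspn and Pola1. Its summed level was 426 and 415 CPM in uninjured, 496 and 447 CPM in empty-vector and 374 and 325 CPM in shIfitm1-labelled limbal cells. Genes of G2 and M phase were lower too, with 0 of 25 over the list alone (1.5e-09, and adjusted p = 0.281 with an estimated correlation). The other 7 lists called, each with adjusted p = 0.768 with an estimated correlation, were higher for immediate early genes (6.4e-07), oxidative phosphorylation (5.2e-06), Wnt and BMP (0.00107), oxidative stress (0.00453) and keratocyte identity (0.0300), each with 0 members adjusted over the list alone, and for corneal differentiation with 2 (0.00182), and lower for the mitochondrial genome with 0 (9.3e-05). Summed levels of the immediate early, Wnt and BMP, and keratocyte lists overlapped between the labels. Without the first empty-vector library 15 lists were called.

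The cycling epithelium was the class in which genes passed, 87 of 13046, 83 higher and 4 lower in the shIfitm1-labelled libraries. The largest rises were in Csgalnact1 (2.56, adjusted p = 0.0165), the vasoactive peptide gene Adm (2.45, adjusted p = 0.0306), Sphkap (2.41, adjusted p = 0.0157), the stress transcription factor gene Atf3 (2.39, adjusted p = 0.0261) and Lypd2 (2.32, adjusted p = 0.0203). Atf3 stood at 838 and 1019 CPM in the uninjured, 451 and 215 CPM in the empty-vector and 1909 and 1585 CPM in the shIfitm1-labelled libraries. A response to dissociation was not separated from the level of Atf3. The genes lower were Crabp2 (-1.65, adjusted p = 0.0165), Adam28 (-0.82, adjusted p = 0.0323), and, outside the naming rule and named after their values were seen, Trpm6 (-1.78, adjusted p = 0.0235) and the helicase gene Pif1 (-0.96, adjusted p = 0.0494). The cluster of mostly uninjured cycling cells held 61 and 12 cells of these libraries against 1 and 6 with empty vector. At Leiden resolution 2 another cycling cluster held 197 and 222 uninjured, 0 and 0 empty-vector and 93 and 3 shIfitm1-labelled cells. Csgalnact1 and Sphkap were also among the largest falls with injury in this class. The mix of cycling clusters was not separated from the 87 calls. The count of 87 was 17 and 16 without the first and the second uninjured library, 228 and 0 without the first and the second empty-vector library, and 0 and 240 without the first and the second shIfitm1-labelled library. DESeq2 called 363.

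Proliferating cells, those with at least 2 UMIs of the G2 and M phase list after thinning, were counted because the series concerns the activation of stem cells. In the epithelium they were 15.6% and 17.7% of uninjured, 34.4% and 30.7% of empty-vector and 15.5% and 23.2% of shIfitm1-labelled cells. Clopper-Pearson 95% intervals were 14.8% to 16.4% and 16.9% to 18.6%, 33.4% to 35.3% and 29.5% to 31.9%, and 14.8% to 16.2% and 22.1% to 24.2%. The means were 16.6% ± 1.49, 32.5% ± 2.61 and 19.3% ± 5.40 (SD, n = 2 each), and an exact two-sided permutation test of 2 against 2 cannot give p below 0.333. The limbal class had lower shares in every library, at 3.49% and 5.66%, 6.96% and 7.86%, and 3.64% and 5.08%. The conjunctival class had 5.00% and 7.56%, 10.5% and 8.40%, and 4.68% and 6.73%. Dividing cells had been clustered into a cycling class apart from both, so low shares in them were fixed by the clustering. An epithelial cluster of unnamed subtype, with Mcm3 among its top genes, had limbal epithelium as its best score. It held 2 and 12 uninjured, 1730 and 706 empty-vector and 1027 and 613 shIfitm1-labelled cells. Over the 11 of 19 epithelial clusters with at least 20 cells in each injured library, the shares overlapped between uninjured (24.2% and 34.1%) and empty-vector libraries (34.0% and 32.6%), so the higher share over the whole epithelium was not separated from the mix of clusters. Free RNA of dividing cells was not separated from these UMIs. The difference between the label and empty vector over the epithelium, -13.2 percentage points, was -20.7 without thinning. It was -9.35 and -17.0 without the first and the second shIfitm1-labelled library.

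**Figure D4:**
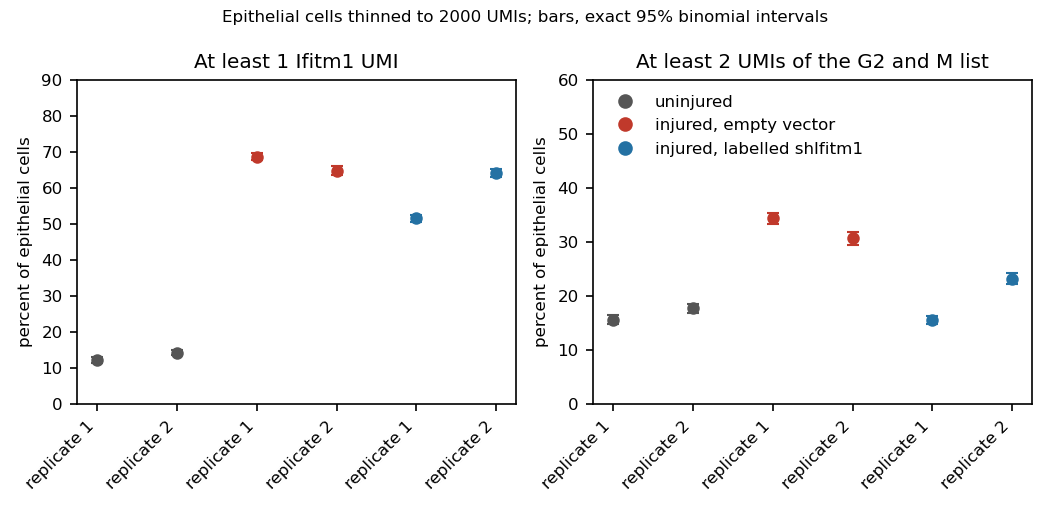
Percent of epithelial cells per library with proliferation UMIs and with an Ifitm1 UMI after thinning to 2000 UMIs, with exact 95% binomial intervals. Proliferating cells reach 34.4% and 30.7% with empty vector and 15.5% and 23.2% in the libraries labelled shIfitm1.

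In the stroma edgeR called 0 of 12723 genes between the labels, with 678 at an unadjusted p under 0.05, 18 by DESeq2 and 197 without the second shIfitm1-labelled library. Keratocyte identity was higher with 1 of 12 adjusted over the list alone, Cd34 at 19.3 and 16.9 CPM against 50.9 and 38.8 CPM, and hypoxia and glycolysis lower with 0 of 22, including Ldha and Slc16a3 (each list adjusted p = 0.00188, adjusted p = 0.967 with an estimated correlation). At resolution 1 the keratocyte cluster held 28 and 1 cells with empty vector and 710 and 64 with the label. An unnamed cluster with Saa3 and Mmp3 among its top genes held 358 and 273 against 183 and 435 cells. This mix of stromal clusters was not separated from the list calls. The smallest p values, all with adjusted p = 0.862, were those of Nrxn3, Krt17 (-2.15), Tnxb (1.75), Cd34 (1.31), Lmo4 (-0.87) and Art4 (0.87). In the conjunctival class 0 of 12599 genes were called by edgeR (505 at an unadjusted p under 0.05, 9 by DESeq2, 8 without the second shIfitm1-labelled library), with Lypd2 at 4.21 among the smallest p values (adjusted p = 0.689). Pericytes, Schwann cells and vascular endothelium gave 0 by edgeR and 0 by DESeq2, with 255, 146 and 490 genes at an unadjusted p under 0.05. Without the second shIfitm1-labelled library they gave 207, 239 and 185 genes, and without the first 1, 11 and 13.

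Immune cells were compared among the 4 injured libraries. In macrophages 0 of 9036 genes passed by edgeR, with 456 at an unadjusted p under 0.05 and 25 by DESeq2, and 172 and 353 genes passed without the first and the second shIfitm1-labelled library. The adhesion gene Icam1 (1.63, adjusted p = 0.193), the interferon regulatory factor Irf1 (1.46), Egr1 (1.78), Ier2 (1.29), Ctla2a (1.89) and Krt17 (-1.83) had the smallest p values, with Icam1 at 40.2 and 40.1 CPM with empty vector and 126 and 123 CPM with the label. Egr1 stood at 130 and 147 against 367 and 582 CPM and Ier2 at 185 and 164 against 388 and 464 CPM. A response to dissociation was not separated from these levels. In neutrophils 0 of 7051 genes passed by edgeR, with 174 at an unadjusted p under 0.05 and 0 by DESeq2, and 377 and 329 without the first and the second shIfitm1-labelled library and 5 without the first empty-vector library. Vcam1 had the smallest p there (2.97, adjusted p = 0.774).

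Against the uninjured libraries, which shows how far the libraries labelled shIfitm1 stood from uninjured tissue, 688 of 17171 epithelial genes passed, 481 higher and 207 lower. Ifitm1 was 4.20-fold higher (adjusted p = 0.0161). The count was 0 without either uninjured library, 269 and 253 without the first and the second empty-vector library, 2135 and 389 without the first and the second shIfitm1-labelled library, and 2025 by DESeq2. Among limbal cells edgeR called 0 of 12881 genes, with 1504 at an unadjusted p under 0.05 and 95 by DESeq2, and 133 without the first shIfitm1-labelled library.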

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

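The tests of free RNA, of the subtype mix and of partial silencing for the Ifitm1 level were chosen after the results were seen. So were those of doublet removal, of uninjured cells in a library, of free RNA in limbal cells and of the shRNA vector. The prediction for the limbal position was written before its result was seen, and that for the common clusters before the share over them was seen.

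Some genes changed with injury in opposite directions in epithelium and stroma in every empty-vector library, and the difference itself was not tested. The log2 fold change in stroma minus that in epithelium was 5.93 for Ddah1 (3.08 and -2.85), -5.76 for Tenm4 (-3.46 and 2.30), 4.84 for Cyp26b1 (2.18 and -2.66), 5.74 for Lamb1 (3.59 and -2.16) and 4.78 for Adm (2.09 and -2.69). They are 5 of 55 such genes at a mean log2 CPM of at least 4 in both tissues. They were named for a log2 fold change of at least 2 in size in both. Of 476 genes called in both tissues 336 went the same way. Adm is a top gene of an epithelial cluster of 665 and 1053 uninjured and 0 and 0 empty-vector cells. The mix of cells in each tissue was not separated from these changes.

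The first library labelled shIfitm1 lay between the uninjured and the empty-vector libraries in epithelium, limbal class and stroma. A different mix of epithelial subtypes, apart from its free RNA, is argued against as the whole cause by the median position of 0.540 within the limbal class. Free RNA of that mix in limbal cells stays open: over the 40 limbal genes raised by injury, from which such RNA takes little, the position was 0.694 with an upper quartile of 0.834, and over the 96 lowered genes 0.505. Cells of an uninjured library in this library stay open as well. Of its keratocyte cluster 28.3% of cells (200 of 706) carried under 2 UMIs of 15 injury genes after thinning, against 98.8% and 99.0% in the uninjured libraries. The share was 3.57% (1 of 28) and 0% (0 of 1) with empty vector and 7.94% (5 of 63) in the other library with the label. Uninjured RNA was not tested. The shRNA vector stays open and cannot be told apart from other differences between libraries, since the other library with the label stood at 0.821 in the limbal class and Ifitm1 was not called lower. A milder burn or an earlier recovery in the tissue of this library may also explain the position. Part of the opposite response may come from the empty-vector libraries shared by both comparisons.

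Ifitm1 was not called lower in the libraries labelled shIfitm1, though in the cycling class both lay below both empty-vector libraries (fold 0.850, 95% interval 0.633 to 1.14). Free RNA filling in for a silenced gene is argued against by Schwann cells and vascular endothelium of these libraries, where Ifitm1 reached at most 0.200 of its epithelial CPM. A subtype mix hiding a fall to 0.5 is argued against by the limbal class, where the lower end of the 95% interval of the fold was 0.830, though without the second shIfitm1-labelled library the log2 fold change was -0.06 and not 0.12. Silencing in a small part of the cells stays open: the share of limbal cells without an Ifitm1 UMI was 0.687 percentage points higher with the label than with empty vector, in groups that overlapped (22.6% and 17.3% against 16.9% and 21.6%), which leaves room for a few transduced cells, and in the cycling class, whose clusters differ between the groups, an Ifitm1 UMI was found in 41.3% and 41.1% of cells with the label against 51.6% and 50.0%. An effect on the protein, a wrong label or a level that had recovered by the time of sampling could not be tested on these data.

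Fewer epithelial cells carried proliferation UMIs in the libraries labelled shIfitm1 than with empty vector. Uneven removal of doublets is argued against by the difference of -12.9 percentage points with doublets removed at the expected rate in every library. Epithelial cells of the uninjured type in clusters of their own are argued against as the whole cause by a difference of -12.9 percentage points. This difference was taken over the 11 of 19 epithelial clusters with at least 20 cells in each injured library (18.3% and 22.6% against 34.0% and 32.6%, with 24.2% and 34.1% in uninjured libraries). Cells of the uninjured type within these clusters, and the mix of the clusters, stay open. A cluster among the 11 held 795 and 473 uninjured, 535 and 104 empty-vector and 1298 and 474 shIfitm1-labelled cells. The shRNA vector stays open and cannot be told apart from differences in burn or recovery, with a log2 fold of -0.0328 for Ifitm1 in the epithelium. A weaker or later wound response in the tissue of these libraries may be a candidate explanation as well, and it was not tested.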

How the results depend on the processing

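Removing doublets at the expected rate, leaving out an epithelial cluster that came mostly from 1 library, leaving out genes higher in epithelium, the common epithelial clusters (with the prediction written before the share over them was seen), the coarser stroma, the fits of 4 injured libraries and all alternatives for the smaller classes were chosen after the data were seen. The other alternatives were chosen before the data were examined. With DESeq2's size factors no count of calls moved by over 1.5 times and no direction turned. Over 344 results for single named genes, with Ifitm1 over all cells and over the epithelium counted apart, leaving out 1 library kept direction and side of the threshold in 1459 cases, lost the call in 469, gained one in 130 and turned the direction in 6, and the other settings gave 2133, 8, 124 and 0. Between the labels, Ifitm1 over all cells and over the epithelium turned direction in 3 further cases with a library left out, and over the epithelium also with doublets at the expected rate. Corneal epithelium, keratocytes at the finer resolution and macrophages with the uninjured libraries were not run, because a library held 1 to 12 cells. Depth limits the classes with few cells and the shares of cells with an UMI, which change with thinning. The causes of the changes below were not tested, except that a left-out library leaves a group with 1 library, assumed to vary like the others.

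By DESeq2, genes between the shIfitm1-labelled and the empty-vector libraries numbered 276 in epithelium, 3 in limbal, 9 in conjunctival and 363 in cycling cells, 18 in stroma and 25 in macrophages, where edgeR called 0, 0, 0, 87, 0 and 0. With injury DESeq2 called 393 in limbal and 181 in conjunctival cells, 18 in pericytes, 31 in Schwann cells and 61 in vascular endothelium, and 2025 epithelial and 95 limbal genes between the shIfitm1-labelled and uninjured libraries. With no filter on low counts, edgeR called 96 epithelial and 201 limbal genes between the labels, 1022 limbal genes with injury, and 1828 epithelial and 531 limbal genes between the shIfitm1-labelled and uninjured libraries, and the covariance of the opposite response was -0.829. It was -0.216 at a mean log2 CPM of at least 5. With only the groups compared in the fit, 261 limbal genes changed with injury and 212 epithelial genes between the shIfitm1-labelled and uninjured libraries. For the limbal class in that comparison, where edgeR called 0 with 1504 at an unadjusted p under 0.05, the count was 7 with the strict cell filter, 9 with doublets kept, 6 at Leiden resolution 0.5 and 15 at resolution 2. With doublets at the expected rate Ifitm1 in epithelium had a log2 fold change of 0.016 between the labels and Schwann cells gave 6 genes with injury. Vascular endothelium gave 14 without genes higher in epithelium.

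With an estimated correlation camera called 0, 0, 0 and 0 lists for epithelium and limbal class with injury and between the labels, and fry called 8 and 1 with injury and 0 and 0 between the labels. The share of proliferating cells, 15.9 percentage points higher with injury, was 11.9 higher after thinning to 1000 UMIs and 10.9 higher at 4 UMIs or more. Between the labels, -13.2 points became -20.7 without thinning and -9.54 at 4 UMIs or more. The share with an Ifitm1 UMI, 53.6 points higher with injury, was 42.4 after thinning to 1000 UMIs and 60.02 without thinning.

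The libraries of replicate 1 carry sample sheet numbers 8, 9 and 10 and those of replicate 2 numbers 37, 38 and 39, and what these sets mark is not given in the sources used here. Deviations of same-numbered libraries (uninjured with empty vector, uninjured with shIfitm1-labelled, and empty vector with shIfitm1-labelled) correlated at -0.0526, 0.0185 and 0.432 over all cells, 0.00388, 0.143 and 0.335 in the epithelium, 0.0229, 0.0583 and 0.209 in the limbal class and 0.263, 0.115 and 0.370 in the stroma. With the replicate block, the counts were 378 limbal, 121 conjunctival, 1 pericyte, 17 vascular and 2082 stromal genes with injury, 1 limbal, 244 cycling, 97 macrophage and 8 neutrophil genes between the labels, 1159 epithelial and 47 limbal genes between the shIfitm1-labelled and uninjured libraries, and 11 class shares. No other count of calls moved by over 1.5 times with the block, and of the single named genes 315 kept, 28 gained and 1 lost the call.

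With each library left out in turn, genes changed by injury ranged from 0 to 4904 in epithelium, 0 to 365 in limbal, 0 to 88 in conjunctival and 1288 to 3314 in cycling cells, 0 to 164 in pericytes, 0 to 215 in Schwann cells, 0 to 262 in vascular endothelium and 0 to 2083 in stroma. Between the labels they ranged from 0 to 600 in epithelium, 0 to 14 in limbal, 0 to 8 in conjunctival and 0 to 240 in cycling cells, 0 to 207 in pericytes, 0 to 239 in Schwann cells, 0 to 185 in vascular endothelium, 0 to 197 in stroma, 0 to 353 in macrophages and 0 to 377 in neutrophils. Between the shIfitm1-labelled and uninjured libraries they ranged from 0 to 2135 in epithelium and 0 to 133 in limbal cells. Lists ranged from 4 to 11 in epithelium between the labels, and in the limbal class from 1 to 7 with injury and 8 to 15 between the labels. Class shares ranged from 0 to 10 and the opposite response from -0.760 to -0.247. Proliferating cells between the labels ranged from -17.0 to -9.35 percentage points and cells with an Ifitm1 UMI, -8.85 with all libraries, from -15.1 to -2.55.

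Directions turned near 0. Between the labels Ifitm1 ranged from -0.29 to 0.21 over all cells (0.21 without the first empty-vector library). In the epithelium it ranged from -0.23 to 0.20 (0.20 without the first empty-vector and 0.03 without the second shIfitm1-labelled library), and in the limbal class from -0.0643 to 0.28 (-0.0643 without the second shIfitm1-labelled library). Ifitm2 ranged between the labels from -0.33 to 0.0777 in epithelium (0.0777 without the first shIfitm1-labelled library) and from -0.0340 to 0.11 in the limbal class (-0.0340 without the first empty-vector and -0.01 without the second shIfitm1-labelled library). With injury limbal Ifitm2 ranged from -0.0272 to 0.13 (-0.0272 without the second empty-vector library). Limbal Ifitm3 ranged between the labels from -0.51 to 0.00015 (0.00015 without the first shIfitm1-labelled library).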

Other observations

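T and NK cells numbered 4 and 0, 38 and 7, and 20 and 13 in uninjured, empty-vector and shIfitm1-labelled libraries, and lymphatic endothelial cells 15 and 9, 14 and 20, and 42 and 7. Schwann cells were 0.663% and 0.477%, 1.07% and 1.44%, and 0.793% and 1.22% of cells, and vascular endothelium 0.791% and 0.277%, 1.08% and 1.10%, and 0.983% and 0.974%.

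Ifitm1 UMIs were counted in immune cells, where free RNA was not separated. After thinning, an Ifitm1 UMI was found in 0 of 15 and 0 of 5 uninjured macrophages, which allows up to 20% and 60%, in 32.7% and 27.9% of empty-vector and in 17.4% and 29.5% of shIfitm1-labelled macrophages. Among neutrophils it was found in 76.9% and 67.6% with empty vector and in 3 of 5 cells and 84.7% with the shIfitm1 label, over the 65 of 482, 506 of 599, 5 of 78 and 248 of 591 neutrophils with at least 2000 UMIs. In Schwann cells, taken as a type without the gene, the share was 15.1% and 3.92% with empty vector and 9.52% and 6.17% with the label, with an interval of 2.66% to 22.6% in the first shIfitm1-labelled library, where macrophages stood at 17.4%. Macrophages there do not stand apart from that background. Pericytes had Ifitm1 at 364 and 399 CPM in the uninjured, 566 and 792 CPM in the empty-vector and 968 and 708 CPM in the shIfitm1-labelled libraries, without passing the test. In vascular endothelium the log2 fold change between the labels was 2.21 by edgeR (BH-adjusted p = 0.481), with 36.2 and 14.5 CPM with empty vector and 189 and 40.1 CPM with the label.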
